A study of Mus musculus with 6 samples.

How the data were processed

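RNA-seq libraries had been made from lungs dissected from C57BL/6 mouse embryos at E12.5. Per the labels' protocols, RNA was extracted with a Qiagen miRNeasy micro kit, cDNA was made with the SMARTer Ultra Low Input v3 kit, and libraries were indexed with Nextera indices and sequenced as 75 bp paired-end reads on an Illumina NextSeq. This kit does not mark strand, so reads of a gene and of an overlapping antisense partner cannot be told apart. Per the submitters' processing notes, the tools were TopHat, Bowtie2 and Cufflinks and the genome was mm10 (GRCm38). Their versions, their roles and the gene annotation are not given in the sources used here.

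The deposited values are FPKM per gene (fragments scaled by transcript length and by the mapped fragments of the library), made by the authors with Cufflinks, per the submitters' processing notes. The table held 24341 genes in 6 libraries. A value of 0.01 FPKM stood where no expression was measured, and 5537 genes had it in all 6 libraries. In mutant library 1, BC065397, Glra4 and Morf4l2, which lie at the same X-chromosome locus, carried a failure mark, and these 3 genes were left out. Loci are those given in the table, counted here from 1. A Cufflinks locus can hold several genes (1928 tested genes shared a locus with another tested gene), so a start or end can lie outside the gene named. Of the symbols, 23135 (95.1%) were found in the RefSeq gene table of GRCm38.

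Read counts were not used here, so absolute depth is unknown. Relative depth was estimated from low values, where the FPKM of a gene with few fragments is a multiple of what 1 fragment is worth. Over 1283 to 1715 genes with values up to 0.3 FPKM, depth relative to control library 1 was 0.80 and 0.53 in control libraries 2 and 3. It was 0.50, 1.27 and 1.08 in mutant libraries 1, 2 and 3. Control library 3 and mutant library 1 were the shallowest and had the most genes at the floor, 7829 and 7837, against 7041 to 7287 in the other libraries. Low values in these 2 libraries carry the larger counting error.

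Values were taken as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 12742 in all. The mutant libraries were compared with the control libraries by limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step and 2-sided p-values adjusted by the Benjamini-Hochberg method. An adjusted p under 0.05 counted as changed. A log2 change on this scale understates the change of genes with low FPKM, so ratios of the group means of FPKM are given beside it as folds. Every adjusted p for a gene is from this test unless another is named. Sin3a was also compared by an exact permutation test of its 6 values.

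There were 35 gene lists, for cell types of the lung and its neighbours, signalling pathways, the cell cycle, stress responses and the SIN3 complex. Lists with at least 3 tested members, 33 in all, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera asks whether the genes of a list rank apart from all other genes. As alternatives, camera was run with an estimated correlation, and fry, which asks whether the genes of a list move on balance in a shared direction, was run on the same lists. For each list the number of changed members is given over all genes tested and adjusted over the list alone.

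The genes named were fixed by a rule. They are Sin3a and Sin3b, then Cdkn1a, Cdkn2a, Cdkn2c, Nkx2-1, Sox2, Sox9, Shh, Fgf10, Bmp4, Epcam and Cdh1, then up to 4 members of each list with the smallest unadjusted p. To these come the 10 highest and 10 lowest log2 changes among changed genes whose groups do not overlap. MicroRNA, small RNA, Gm and Rik gene models are left out of the last part. Members of a list named only to complete a count of 5 or fewer, or as the members farthest from the rest, were chosen after their values were seen: Actc1, Col1a2, Col3a1, Gli1, Hoxa5, Krt19, Mycn, Nppa and Rrm2. Some genes that the rule or a count would name are not reported here.

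The alternatives were other pseudocounts, filters, scalings, settings of the variance step, thresholds, a block for the replicate number, and leaving out each library in turn. The groups, the lists, the rule for named genes, the main test and these alternatives were fixed before the data were examined. Added after seeing the data were a correction for GC content and transcript length, the same with the replicate block, a covariate for the presence of Y-linked transcripts, and the estimated correlation after the GC correction. The GC and length correction fitted each library's deviation from the gene means by loess (span 0.3) on GC content and log length of GENCODE M21 transcripts. Of the tested genes, 12277 (96.4%) had both values. Python 3.11.15 with matplotlib 3.10.9 drew the plots.

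The fit was tested on simulated data, with normal values for 12742 genes around the observed means. Variances were drawn from the distribution that the empirical Bayes step had fitted. Of 100 genes simulated at a 2-fold change 81% were recovered, and of 100 at a 4-fold change 98%. These genes were drawn from the more abundant ones and shifted on the log2(FPKM + 1) scale, so the rates do not cover genes with low FPKM. There were 9 false calls, 4.79% of the calls, and none had the wrong sign. Since the simulated data met the fit's own assumptions, that share does not test those assumptions on the real libraries. In simulated lists, camera called the shifted list and 0 of 200 unshifted ones. With an estimated correlation the shifted list had an unadjusted p of 4.48e-04, against an adjusted p of 7.12e-30 at the preset. In that form 0 of the 200 unshifted lists had an unadjusted p under 0.05, so it was the stricter form on independent genes too. The simulated genes varied independently, so this does not test camera on lists whose genes vary together. In the lists called below, estimated correlations ran from -0.05 (CDK inhibitors) to 0.72 (heart muscle). With the observed GC trends added, 78% of the 2-fold changes were recovered without the correction and 82% with it.

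The labels number the libraries 1 to 3 in each group and do not say whether a number marks a shared litter or day, nor which embryos a library came from. The p-values therefore measure only the spread between these libraries, which may be technical in part.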

Results

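Whole lungs of mouse embryos at E12.5 were profiled by RNA-seq in 2 groups of 3 libraries. The mutant group was Shh-Cre;Sin3a flox/flox and the control group Shh-Cre;Sin3a flox/+, so both carried the Cre recombinase and the controls kept a functional Sin3a allele. Shh-Cre is active in the epithelium of the early lung, while the libraries held RNA of all lung cells. Summed FPKM was 729525, 738697 and 676961 in control libraries 1 to 3 and 640011, 645621 and 627190 in mutant libraries 1 to 3. These sums are not depths, and relative depth ranged from 0.50 to 1.27 times that of control library 1. Pearson's r of log2 values over genes was 0.975 to 0.978 within the control group, 0.960 to 0.978 within the mutant group and 0.962 to 0.973 between the groups. These correlations run across genes, which are not independent replicates. Y-linked transcripts such as Eif2s3y were high in control library 2 and mutant library 1 and Xist was high in the other libraries, so each group held 1 library with a male pattern.

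Sin3a, the scaffold subunit of a histone deacetylase corepressor complex, had nearly the same FPKM in both groups. It measured 19.5, 18.6 and 18.6 FPKM in the control libraries and 18.8, 16.3 and 18.8 FPKM in the mutant libraries, for the locus on chromosome 9 from 57072040 to 57128368 (GRCm38). The log2 change was -0.07 (SE 0.09, n = 3 per group, adjusted p = 0.68), and the exact permutation test gave p = 0.6 (2-sided, the smallest possible being 0.1). The 95% interval of the change ran from a log2 change of -0.29 to 0.14, from a fall of 18.4% to a rise of 10.6%. The values per gene count all exons in all lung cells and the labels do not name the floxed exons, so they do not check the genotype labels. Its paralog Sin3b measured 159 ± 23.4 FPKM in controls and 170 ± 17.3 FPKM in mutants (SD, n = 3, adjusted p = 0.68). Of 19 measured SIN3 complex genes, 0 changed over all genes tested and 0 when adjusted over the list alone. The largest difference, in Fam60a, was a log2 change of -0.66 (adjusted p = 0.074), and camera gave the list an adjusted p of 0.57 (0.71 with an estimated correlation, 0.36 by fry).

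Which transcripts differed between lungs of the 2 genotypes was the question of the comparison. The surfactant gene Sftpc, a marker of distal lung epithelium, was 91.8-fold lower in mutants, at 0.586 ± 0.156 FPKM against 53.7 ± 6.76 FPKM in controls (SD, n = 3 per group). Keratins Krt8 and Krt18 fell to 13.7 ± 1.14 and 21.4 ± 3.24 FPKM from 41.6 ± 3.97 and 57.9 ± 3.41 FPKM. In the opposite direction, the surfactant gene Sftpa1 rose 12.1-fold, to 29.4 ± 5.53 FPKM from 2.44 ± 1.22 FPKM, and the growth factor gene Fgf10 rose 3.80-fold. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 3.45-fold, from 2.03 ± 0.491 to 7.00 ± 1.11 FPKM. The hedgehog target genes Hhip and Ptch1 fell 3.52-fold and 2.14-fold, while their list as a whole was not called (camera adjusted p = 0.17).

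**Figure D1:**
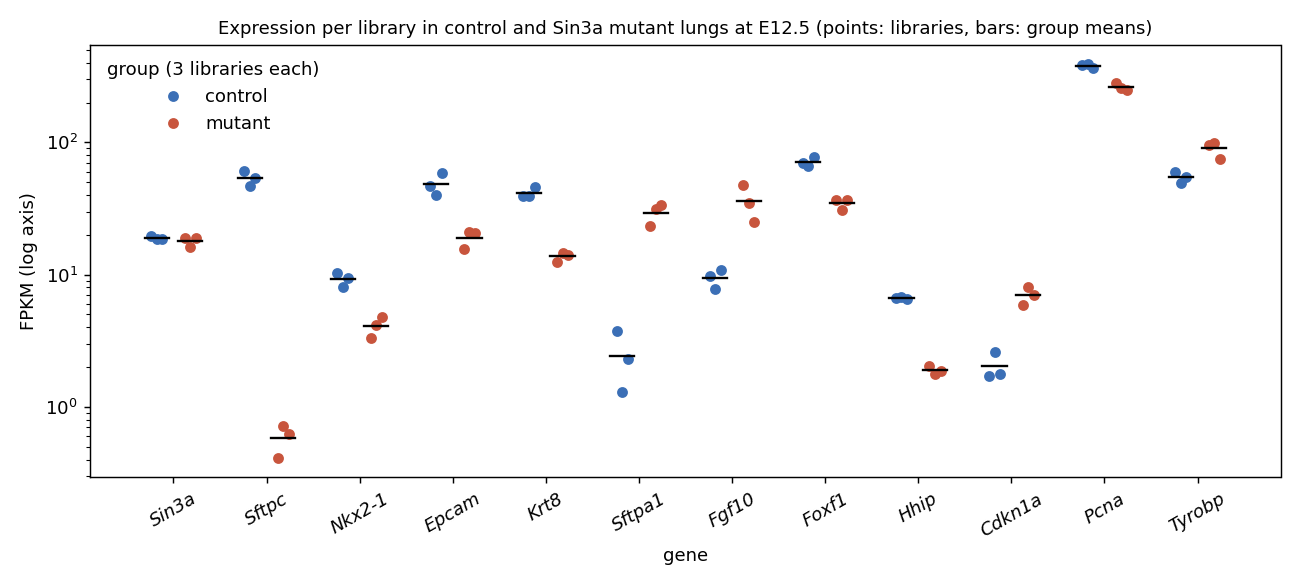
FPKM of 12 genes in each of the 6 libraries, on a log axis, with control libraries in blue, mutant libraries in red and black bars for the group means. The groups overlap for Sin3a, and for the other genes shown all 3 mutant libraries lie on the same side of all 3 control libraries, with Sftpc falling from a mean of 53.7 to 0.586 FPKM.

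Limma called 426 of 12742 tested genes at an adjusted p under 0.05, 218 higher and 208 lower in the mutant (48.8% lower). The change was at least 1 on the log2 scale for 38 of the higher and 62 of the lower genes, and 2935 genes had an unadjusted p under 0.05. All 426 had groups that did not overlap, as had 3757 of the tested genes (29.5%, where chance gives 10%). With globin and small RNA genes left out and the rest rescaled to a common sum, the median change of all genes moved by 0.114 and the calls became 841 higher and 173 lower (17.1% lower). The number of calls rested on the libraries used: it was 61, 66 and 64 without control library 1, 2 or 3, and 795, 52 and 283 without mutant library 1, 2 or 3. Of the 62 called genes that the rule names, 20 stayed called whichever library was left out and 42 did not. The 20 were the 10 genes with the lowest changes, Sftpa1, Hdc, Ctnna2, Lrfn5, Asic4, Krt8, Krt18, Hhip, Foxf1 and Wnt2.

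The 10 lowest changes were those of Sftpc, Mia, Aldh1a7, Cldn10, Sfta2, Cckar, Wfdc2, Tmem54, Rab25 and Cym. Sftpc, on chromosome 14 from 70520942 to 70524081, had a log2 change of -5.11 (SE 0.13, adjusted p = 9.06e-06). Sfta2, a surfactant-associated gene, was 21.6-fold lower (9.62 ± 1.70 against 0.445 ± 0.0779 FPKM) and Aldh1a7 was 19.8-fold lower. Wfdc2, an epithelial secreted protein gene, was the most abundant of the 10 in controls and was 5.92-fold lower (114 ± 4.77 against 19.3 ± 3.70 FPKM). Cldn10, which encodes a tight junction protein, was 17.8-fold lower, and Rab25, a GTPase gene of epithelial membrane traffic, was 19.6-fold lower. Cym was 41.1-fold lower, with a mutant mean of only 0.102 FPKM, Cckar 18.9-fold, Tmem54 16.6-fold and Mia 11.0-fold. Adjusted p-values of these 10 genes were at most 0.00202, and each of the 10 stayed under 0.05 whichever library was left out.

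The 10 highest changes were those of Sftpa1, Hdc, Reg4, Fgf10, Pthlh, Pnmt, Slc2a3, Ctnna2, Lrfn5 and Asic4. Sftpa1, on chromosome 14 from 41131788 to 41136373, had a log2 change of 3.19 (SE 0.26, adjusted p = 0.00205). Hdc, the histidine decarboxylase that makes histamine, rose 10.8-fold, from 1.09 ± 0.352 to 11.8 ± 1.67 FPKM. Reg4 rose 40.4-fold, from a control mean of only 0.129 FPKM to 5.23 ± 2.11 FPKM. Pnmt, the enzyme that makes adrenaline, rose 8.26-fold, and Pthlh, the parathyroid hormone-related peptide gene, rose 5.89-fold. The glucose transporter gene Slc2a3 rose 3.41-fold, from 9.08 ± 0.880 to 30.9 ± 8.14 FPKM. Of genes known from neurons, Lrfn5 rose 4.66-fold, Asic4 4.74-fold and Ctnna2 3.43-fold, while 0 of 14 members of the neural crest and neuron list changed. Without control library 1 the calls of Reg4 and Slc2a3 ended (adjusted p = 0.053 and 0.051), without control library 3 those of Reg4, Pnmt and Pthlh (each 0.056), and without mutant library 2 that of Pthlh (0.058). Fgf10 had adjusted p-values of up to 0.087 when a control library or mutant library 2 was left out.

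Lung epithelial genes were lower as a group. Of 25 tested members, 10 fell and 0 rose over all genes, and 16 fell and 1 rose when adjusted over the list alone. The median log2 change was -0.83, and camera called the list down (adjusted p = 2.36e-12, and adjusted p = 0.45 with an estimated correlation). Epcam, an epithelial surface protein gene, fell from 48.6 ± 9.67 to 19.1 ± 3.09 FPKM (2.55-fold, adjusted p = 0.014). The lung endoderm transcription factor gene Nkx2-1 fell from 9.26 ± 1.07 to 4.08 ± 0.730 FPKM (2.27-fold, adjusted p = 0.019), and the forkhead factor gene Foxa1 fell 3.77-fold (adjusted p up to 0.078 with 1 library left out). Cdh1, which encodes E-cadherin, measured 3.69 ± 0.833 against 1.55 ± 0.363 FPKM (adjusted p = 0.051). The member that rose over the list alone was the keratin gene Krt19, with a log2 change of 0.27. Shh was under the filter, with 1.08 ± 0.255 FPKM in controls and 0.360 ± 0.117 FPKM in mutants. The call of Nkx2-1 ended when any control library or mutant library 2 was left out (adjusted p up to 0.099) and that of Epcam without control library 1 or 3 or mutant library 2 (up to 0.074), while Krt8, Krt18 and Rab25 stayed called.

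Genes of distal tip progenitors moved both ways. Of 15 tested, 4 fell (Sftpc, Irx2, Mycn and Etv4) and 1 rose (Gata6), with the same counts adjusted over the list alone. Etv4, a target of FGF signalling, was 1.81-fold lower and Irx2 2.84-fold lower, while Gata6, an endoderm transcription factor gene, rose 1.74-fold, from 29.3 ± 2.36 to 50.9 ± 2.79 FPKM. Sox9 measured 8.99 ± 0.763 FPKM in controls and 9.18 ± 1.18 FPKM in mutants (adjusted p = 0.93), and Bmp4 19.2 ± 1.84 and 24.6 ± 3.41 FPKM (adjusted p = 0.17). Camera did not call the list (adjusted p = 0.17, and adjusted p = 0.45 with an estimated correlation), whereas fry gave it an adjusted p of 0.00999. In the proximal airway list, 1 of 6 tested members changed: Sox2, which marks proximal epithelium, fell 4.41-fold from 1.64 ± 0.265 FPKM (adjusted p = 0.027). Krt14 had a log2 change of 0.68 and passed only when adjusted over the list alone, where 1 member rose and 1 fell. Camera gave that list an adjusted p of 0.77. The calls of Sox2, Irx2, Etv4 and Gata6 each ended when any of 4 libraries was left out (adjusted p up to 0.11, 0.13, 0.15 and 0.084).

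Hedgehog response genes held 5 members that fell and 1 that rose among 14, or 6 and 3 adjusted over the list alone. Hhip, a hedgehog-binding inhibitor and target, fell from 6.65 ± 0.148 to 1.89 ± 0.140 FPKM (adjusted p = 0.0016). Foxf1, a mesenchymal forkhead gene, fell from 71.2 ± 5.40 to 34.6 ± 3.42 FPKM (2.06-fold, adjusted p = 0.0054). The receptor gene Ptch1 fell (adjusted p = 0.039), as did the effector gene Gli1, with a log2 change of -0.64. Boc, a hedgehog co-receptor gene, rose 1.56-fold. Fry gave the list an adjusted p of 0.020. Camera did not call it, except down with globin and small RNA genes left out (adjusted p = 0.045, median 0.019). The calls of Hhip and Foxf1 held whichever library was left out, and those of Ptch1 and Boc did not (adjusted p up to 0.14 for each).

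Lung mesenchyme genes were higher as a group, with 5 of 22 that rose and 2 that fell, or 12 and 2 adjusted over the list alone (median log2 change 0.34, camera adjusted p = 2.19e-04, and adjusted p = 0.18 with an estimated correlation). Those that rose were Fgf10, Pdgfra, Hoxa5, Col1a2 and Col3a1. Pdgfra, a growth factor receptor gene of fibroblasts, rose 1.59-fold, from 30.6 ± 0.819 to 48.6 ± 2.01 FPKM (adjusted p up to 0.090 with 1 library left out). The members that fell were Foxf1 and Wnt2. Wnt2, a mesenchymal ligand gene, fell from 87.5 ± 4.26 to 49.4 ± 2.85 FPKM (1.77-fold, adjusted p = 0.0056). Fgf10, on chromosome 13 from 118714699 to 118792573, measured 9.47 ± 1.52 FPKM in controls and 36.0 ± 11.4 FPKM in mutants (log2 change 1.78, SE 0.23, adjusted p = 0.0123).

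FGF, WNT, BMP and NOTCH signalling lists were not called by camera (adjusted p = 0.24, 0.17, 0.34 and 0.84). FGF signalling held 1 riser, Fgf10, and 1 faller, Etv4, among 14, or 2 and 3 adjusted over the list alone. In WNT signalling, Sfrp1, which encodes a secreted WNT antagonist, rose 1.52-fold and Wnt2 fell among 20, or 2 and 1 over the list alone. Bambi, a BMP pseudoreceptor gene, was the only changed member among 14 in BMP signalling and rose 1.38-fold, with 3 that rose over the list alone. The calls of Sfrp1 and Bambi each ended when any of 4 libraries was left out (adjusted p up to 0.11 and 0.14). Of 13 NOTCH signalling genes 0 changed over all genes, and over the list alone 1 fell, Lfng (log2 change -0.50). Smooth muscle and cartilage genes had 0 changed members of 14 and 11 by either count, with camera adjusted p = 0.57 and 0.65.

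CDK inhibitors and p53 targets were higher as groups by camera. Of 4 tested inhibitors, Cdkn1a rose (log2 change 1.40, SE 0.16, adjusted p = 0.0092), and 2 rose adjusted over the list alone, the other being Cdkn2c at 1.03 ± 0.359 and 2.32 ± 0.588 FPKM (adjusted p over all genes 0.091). Cdkn2a was at the floor of 0.01 FPKM in all 6 libraries. Camera gave the inhibitors an adjusted p of 0.014 (adjusted p = 0.35 with an estimated correlation), and 0.19 with no filter on low genes. Of 22 p53 targets, 3 rose over all genes (Cdkn1a, Eda2r and Plk2) and 6 over the list alone, with 0 that fell by either count, and camera gave an adjusted p of 0.022 (adjusted p = 0.35 with an estimated correlation, median log2 change 0.16, or 0.26 with globin and small RNA genes left out). That call ended without control library 1 (adjusted p = 0.086) and at a mean of at least 5 FPKM (adjusted p = 0.17, median 0.083, 0 members changed). Eda2r, a death-domain receptor gene, rose 3.21-fold and the kinase gene Plk2 1.39-fold, calls that each ended when any of 5 libraries was left out (adjusted p up to 0.12 and 0.19). The call of Cdkn1a ended without control library 1 or 3 or mutant library 2 (adjusted p up to 0.066), with log2 changes of 1.31 to 1.80 over all alternatives.

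Cell cycle genes were lower by small amounts. Of 35 DNA replication genes, 34 had negative changes and 5 fell over all genes, and 22 fell adjusted over the list alone (median log2 change -0.33, camera adjusted p = 3.35e-11, and adjusted p = 0.058 with an estimated correlation). The 5 were Pcna, Rfc4, Rrm2, Tyms and Ccne1. Pcna, the sliding clamp of DNA polymerases, fell from 378 ± 11.8 to 262 ± 14.5 FPKM (1.44-fold, adjusted p = 0.020). Ccne1, which encodes cyclin E, fell from 80.9 ± 1.75 to 58.1 ± 4.17 FPKM. All 27 G2 and mitosis genes had negative changes, 1 fell over all genes and 12 over the list alone (median -0.27, camera adjusted p = 1.11e-07, and adjusted p = 0.35 with an estimated correlation). That gene was Cdk1, the mitotic kinase, which fell from 144 ± 3.02 to 106 ± 4.69 FPKM. With globin and small RNA genes left out, both lists stayed called, with smaller medians of -0.206 and -0.140 and with 2 and 0 members that fell. The calls of Pcna, Rfc4, Tyms, Ccne1 and Cdk1 each ended when any control library or mutant library 2 was left out (adjusted p up to 0.16), and that of Rfc4 also after a GC and length correction (0.085).

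Senescence secretory genes and pro-apoptotic genes were not called as lists (camera adjusted p = 0.19 for each). In the first, Igfbp5 rose 1.54-fold, from 139 ± 2.84 to 214 ± 2.64 FPKM, and Plaur fell from 9.81 ± 0.270 to 6.54 ± 0.535 FPKM, among 11 members, or 2 and 1 adjusted over the list alone. Among 15 pro-apoptotic genes, Bcl2l11, which encodes the BH3-only protein Bim, rose 1.62-fold and was the only changed member. Over the list alone 3 rose, the others being Casp9 and Fas, with log2 changes of 0.40 and 0.91. Leaving out 1 library ended the calls of Igfbp5, Plaur and Bcl2l11 (adjusted p up to 0.072, 0.17 and 0.13).

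All 16 macrophage and leukocyte genes had positive changes, 2 rose over all genes and 11 over the list alone (median log2 change 0.58, camera adjusted p = 6.38e-07, and adjusted p = 0.45 with an estimated correlation). Those 2 were Tyrobp, at 54.5 ± 5.27 and 89.9 ± 13.1 FPKM, and Cx3cr1, which rose 1.68-fold. Of 19 endothelial genes 17 had positive changes and 1 rose, Kdr, a VEGF receptor gene, from 11.3 ± 0.672 to 16.2 ± 0.763 FPKM, with 2 over the list alone (median 0.25, or 0.17 without control library 2, camera adjusted p = 6.86e-04, and adjusted p = 0.45 with an estimated correlation). Erythroid genes were lower, with 2 of 14 that fell, the globin genes Hbb-y (2.14-fold) and Hbb-bt (2.70-fold), and 7 over the list alone (median -0.60, camera adjusted p = 1.79e-04, and adjusted p = 0.45 with an estimated correlation). That median was -0.399, -1.02 and -0.911 without control library 2, control library 3 and mutant library 3, -0.915 at a mean of at least 5 FPKM and -0.335 with globin and small RNA genes left out. The call of Hbb-y ended without any 1 library but control library 3 (adjusted p up to 0.19) and under quantile normalization, where its change was about 0. Quantile normalization gives each rank the same value in every library, so a change of a gene that keeps its rank cannot show there. Leaving out 1 library also ended the calls of Tyrobp, Cx3cr1, Kdr and Hbb-bt (adjusted p up to 0.17, 0.18, 0.17 and 0.15). Globin transcripts made up 5.01%, 6.21% and 3.40% of summed FPKM in the control libraries and 2.30%, 2.37% and 3.17% in the mutant libraries.

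Heart muscle genes were also higher. Of 8 tested members, all with positive changes, Myl7 and Myl4 rose over all genes and 3 rose over the list alone (median 0.70, camera adjusted p = 0.0033, and adjusted p = 0.45 with an estimated correlation), with a median of 0.15 when low genes were not filtered. Myl7, the atrial myosin light chain gene, measured 132 ± 15.4 and 238 ± 19.1 FPKM. Actc1 and Nppa had log2 changes of 0.11 and 0.26 (adjusted p = 0.90 and 0.81). Among 10 mesothelial genes Lrrn4 rose 1.47-fold, the only changed member by either count, and camera gave the list an adjusted p of 0.045 (adjusted p = 0.52 with an estimated correlation). That call ended without control library 3 or mutant library 1 (0.13 and 0.31), with no intensity trend (0.058) and after the GC and length correction (0.093). In the neural crest and neuron list, 0 of 14 changed by either count (camera adjusted p = 0.67, or 0.027 without control library 2). REST targets, genes that the REST repressor silences outside neurons, had 0 of 7 changed over all genes and 2 that rose over the list alone, among them Kcnh2 (camera adjusted p = 0.31). The skeletal muscle, liver, and oesophagus and stomach lists had 0 changed members over all genes among 6, 4 and 6, with camera adjusted p = 0.17, 0.65 and 0.61. Camera called the skeletal muscle list down with globin and small RNA genes left out (adjusted p = 0.021) and without control library 3 or mutant library 2 (0.0033 and 0.030). Over the list alone 1 liver gene rose and 1 fell, likewise for oesophagus and stomach, and 0 skeletal muscle genes changed. Among germline genes only 2 were tested, too few for camera, and Asz1 fell 3.78-fold, over all genes and over the list alone. Leaving out 1 library ended the calls of Myl7, Myl4, Lrrn4 and Asz1 (adjusted p up to 0.086, 0.17, 0.19 and 0.11).

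Ribosomal protein genes were lower by a small amount, with 36 of 37 changes negative, 2 that fell over all genes (Rpl30 and Rpl5) and 4 over the list alone (median -0.20). Camera called the list down (adjusted p = 2.10e-07, and adjusted p = 0.45 with an estimated correlation), but under quantile normalization the median was 0.02 and the adjusted p 0.99. The median was -0.066 with globin and small RNA genes left out and -0.10 after the GC and length correction, which ended the calls of Rpl30 and Rpl5 (adjusted p = 0.11 and 0.13). Leaving out any of 5 libraries also ended both calls. Hypoxia response genes were higher, with 2 of 17 that rose, the glycolytic regulator Pfkfb3 (1.90-fold) and Ndrg1 (1.92-fold), and 5 that rose and 2 that fell over the list alone. Their camera adjusted p was 0.045 (adjusted p = 0.45 with an estimated correlation). It rose to 0.12, 0.054, 0.17 and 0.074 without control library 1, control library 2, mutant library 1 and mutant library 3. It was also over 0.05 at a mean of at least 5 FPKM (0.059), with globin and small RNA genes left out (0.053) and after the GC and length correction (0.0504). Immediate early genes held 1 riser of 11, Klf6 (1.40-fold), with 3 over the list alone, and interferon response genes 0 of 12 by either count (camera adjusted p = 0.31 and 0.14, the latter 0.049 without control library 3). The Y-linked and Xist list had 0 changed of 5 by either count (camera adjusted p = 0.99), and no mitochondrially encoded gene was measured. The calls of Pfkfb3, Ndrg1 and Klf6 ended with 1 library left out (adjusted p up to 0.11, 0.12 and 0.16).

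**Figure D2:**
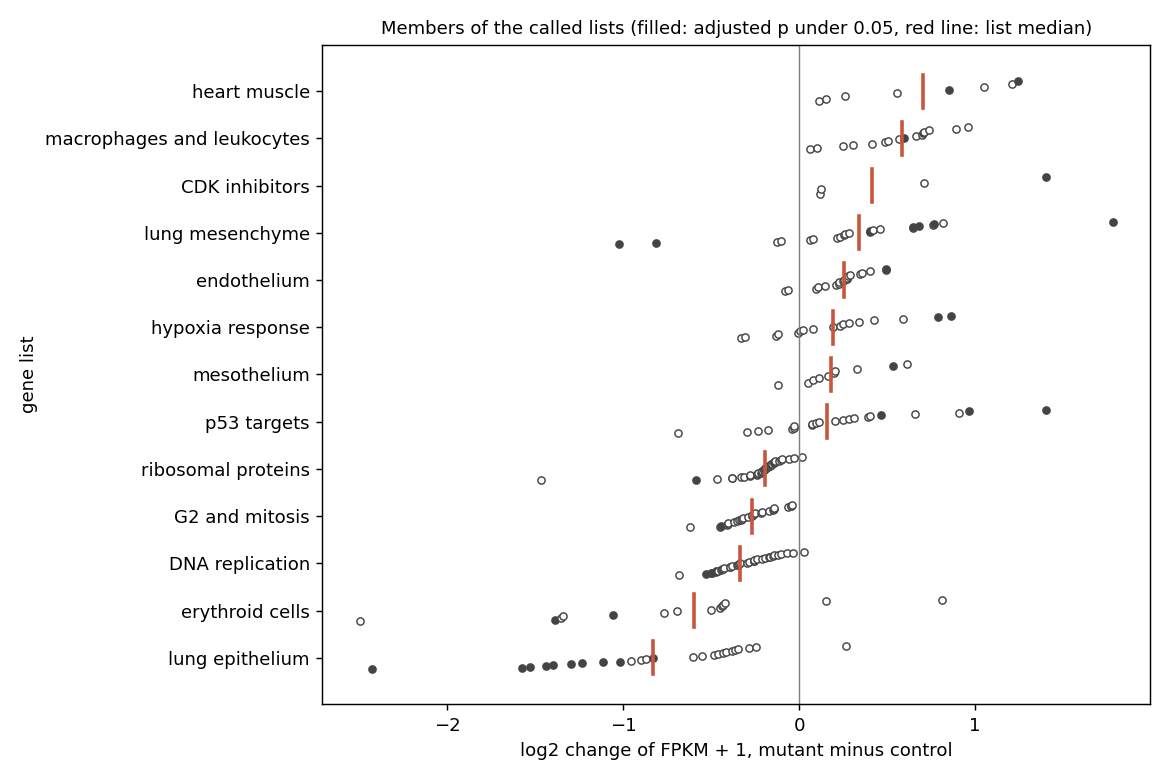
Log2 change of FPKM + 1, mutant minus control, of every tested member of the 13 gene lists called by camera, with filled points for members with an adjusted p under 0.05 and a red line at the list median. Medians run from -0.83 for lung epithelium to 0.70 for heart muscle, and lung mesenchyme holds members on both sides.

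Camera called 13 of 33 lists, 8 up and 5 down, and with an estimated correlation 0 were called (lowest adjusted p = 0.058, 4 lists with an unadjusted p under 0.05). High estimated correlations do not account for every lost call. For DNA replication, p53 targets, lung mesenchyme and CDK inhibitors the estimates were below the preset of 0.01 (0.0060, 0.0084, -0.020 and -0.050). Fry called 11 lists with a shared direction and 23 for change in either direction. Of the lists that camera called, fry did not call macrophages and leukocytes or ribosomal proteins (adjusted p = 0.096 for each). Nor did it call endothelium (0.11), heart muscle (0.15), erythroid cells (0.16) or mesothelium (0.20). Fry called distal tip progenitors, hedgehog response, REST targets and immediate early genes (0.00999, 0.020, 0.027 and 0.034), which camera did not. Library 3 of the mutants stood apart in base composition: the tenth of genes with the lowest GC content deviated by a median of -0.41 on the log2 scale there, against 0.25 in mutant library 1 and -0.07 to 0.12 in the other libraries. A correction for GC content and transcript length raised the count of changed genes to 1357, which included 411 of the 426.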

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

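The GC and length correction, alone or with the replicate block, the estimated correlation after it and the sex covariate were chosen after seeing the data. Of 426 changed genes (218 higher, 208 lower), all kept their direction in every alternative in which they were tested, except Hbb-y. Its change came to about 0 under quantile normalization, which cannot show a change of a gene that keeps its rank. Without the filter 242 genes changed (105 higher, 137 lower), with more genes tested. At a mean of at least 5 FPKM 284 changed (146 higher, 138 lower), with fewer genes tested. Leaving out globin and small RNA genes gave 1014 (841 higher, 173 lower), of which 364 were among the 426; its rescaling lifted the mutant libraries. Asking for a log2 change of at least 1 gave 100 (38 and 62), and an adjusted p under 0.1 gave 1138 (576 and 562). The GC and length correction gave 1357 (655 and 702); why the count rose was not tested further. Counts stayed within 1.5 times, 325 to 503, under other pseudocounts, median-of-ratios scaling, quantile normalization, no intensity trend, robust hyperparameters and the sex covariate.

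Leaving out each library in turn gave 52 to 795 changed genes, 17 to 362 higher and 35 to 433 lower, with fewer samples per fit. The lowest count was without mutant library 2 and the highest without mutant library 1. Of 62 called genes among those named, 20 stayed called whichever library was left out. The lists called numbered 11 to 14, and 10 of the 13 stayed called; p53 targets, mesothelium and hypoxia response did not. The log2 change of Sin3a lay between -0.12 and 0.05 over all alternatives and was never called. No list was called with an estimated correlation (0 lists, also 0 after the GC correction), against 11 by fry, not all of them among the 13. The ribosomal protein list turned direction under quantile normalization (median 0.0174, adjusted p 0.986); the cause was not tested.

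With a replicate block the count was 52 (20 higher, 32 lower) and 12 lists were called, the hypoxia list no longer (adjusted p = 0.0513, and 0.0510 with the GC correction too), and with the GC correction and the replicate block it was 208 (105 and 103). Libraries of the same number did not deviate together (correlations of -0.09, -0.08 and -0.03, against -0.03 to 0.09 for different numbers), so no library correlated best with its own number. Depth relative to control library 1, from 0.50 to 1.27, limits low genes most in control library 3 and mutant library 1.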

Other observations

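The tests here other than the splits of the uncorrected libraries rest on choices made after the results were seen, among them the correction for GC content and length, as do the gene families of this paragraph and the next. Camera p-values of the families were adjusted over these chosen families alone. Since the families were picked from the same data, these p-values cannot be set beside those of the lists fixed beforehand. Of 31 ribosome biogenesis genes 7 fell and 0 rose, with a median log2 change of -0.32 and a camera adjusted p of 4.24e-12 (adjusted p = 0.016 with an estimated correlation). They included the nucleolar genes Ncl (108 ± 3.73 FPKM in controls and 78.6 ± 7.24 FPKM in mutants, SD, n = 3) and Nop56 (205 ± 4.45 and 151 ± 6.75 FPKM), the RNA helicase gene Ddx21 (14.0 ± 0.405 and 9.54 ± 0.396 FPKM) and Dkc1. Mitochondrial ribosome genes had 2 of 77 that fell (median -0.24) and proteasome genes 0 of 37 (median -0.23). Their camera adjusted p-values were 4.24e-12 and 4.29e-08, and each had an adjusted p of 0.11 with an estimated correlation. Among 13 claudin genes 4 fell and 0 rose (median -0.46, camera adjusted p = 2.09e-06, and adjusted p = 0.031 with an estimated correlation). Besides Cldn10 these were Cldn9 (14.2-fold lower), Cldn18 (7.43-fold lower) and Cldn6 (2.96-fold lower). The lung epithelium list, which holds Cldn6 and other claudin genes, was lower in the same libraries (median -0.83).

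Collagen genes had 6 of 27 that rose and 0 that fell, with a median log2 change of 0.31 (camera adjusted p = 3.51e-07, and adjusted p = 0.14 with an estimated correlation). Col6a1 rose from 23.4 ± 0.587 to 43.1 ± 3.77 FPKM and Col6a2 from 20.4 ± 1.88 to 36.3 ± 4.38 FPKM, beside Col1a2, Col3a1, Col5a2 and Col23a1. The lung mesenchyme list, which shares Col1a2 and Col3a1 among others, was higher in the same libraries (median 0.34). Lysosomal genes had 5 of 31 that rose and 0 that fell (median 0.29, camera adjusted p = 5.76e-09, and adjusted p = 0.11 with an estimated correlation). Macrophage and leukocyte markers were higher in the same libraries (median 0.58). The 5 lysosomal genes were the cathepsin genes Ctsb, Ctsd and Ctsf, the progranulin gene Grn (55.2 ± 1.62 and 87.8 ± 13.2 FPKM) and Cln6. Of 44 replication-dependent histone genes 3 fell, Hist1h2ae, Hist1h2be and Hist1h4h (median -0.42, camera adjusted p = 1.27e-05, and adjusted p = 0.11 with an estimated correlation). Complex I genes had 2 of 37 that fell (median -0.16, camera adjusted p = 2.09e-05, and adjusted p = 0.19 with an estimated correlation). Under quantile normalization their median came to -0.00245 (camera adjusted p = 0.70). Potassium channel genes had 3 of 27 that rose (median 0.06, camera adjusted p = 0.017, and adjusted p = 0.11 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.12), with globin and small RNA genes left out (0.090) and after the GC and length correction (0.096). The medians of these families kept their sign under all 3 scaling alternatives, but some shrank and others grew. With globin and small RNA genes left out they were -0.198 for ribosome biogenesis, -0.108 for the mitochondrial ribosome, -0.0973 for the proteasome, -0.0269 for complex I and 0.144 for potassium channels. Quantile normalization gave -0.136 for the mitochondrial ribosome, -0.0968 for the proteasome and 0.0036 for potassium channels. The GC and length correction gave -0.158 and -0.0858 for the mitochondrial ribosome and complex I.

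Splits of the 6 libraries 3 against 3 number 10, too few for a share under 0.05. The real split called 426 genes and the highest other split 4, and 1 of the 10 splits, the real one, called as many as 426. After the GC and length correction the real split called 1357 genes and the highest other split 4, again 1 of 10.

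Sin3a had nearly the same FPKM in the mutant and control libraries. If the level of the lung epithelium list follows the genotype, which was not tested, it argues against a single library with the wrong label. The mean log2 level of the list was 3.16 to 3.52 in the control libraries and 2.22 to 2.69 in the mutant libraries. The lowest control lay 0.465 above the highest mutant, more than the larger SD of a group, 0.251; this does not test an exchange of the whole groups. A candidate explanation that stays open is that the epithelium made too small a part of the lung RNA for its loss of Sin3a to show, since the 95% interval allows a fall of up to 18.4%. The controls were Shh-Cre;Sin3a flox/+, so their epithelium could also have lost Sin3a from the floxed allele, which would make the difference smaller. A deletion that leaves a transcript still counted over its other exons could also give this, and was not tested.

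Epithelial genes fell by unequal amounts on the log2(FPKM + 1) scale. The 95% interval of 12 of 25 lung epithelium genes left out the list's median, 6 that fell more and 6 that fell less or were higher. This scale shrinks the changes of genes with low FPKM, so a common factor would also give unequal values. It does not account for Rab25, the member that fell most, which at 6.08 FPKM in controls was 19.6-fold lower. Krt8, at 41.6 FPKM in controls, was 3.03-fold lower. Folds of FPKM of Nkx2-1, Epcam and Foxa1 lay closer to that of Krt8, at 2.27, 2.55 and 3.77. With a pseudocount of 0.01 the list's median was -1.09. A GC or length trend between libraries as the whole cause is argued against by the list's median after the correction, -0.84 against -0.83 before (bootstrap SD 0.200). That SD came from resampling the list's genes and does not measure the spread between libraries. For the list's falls, a lower share of epithelial cells cannot be told apart from a change within those cells. Members expressed elsewhere would fall less, and members with low FPKM would show smaller changes on this scale. A lower share of epithelial cells does not account for Sftpa1, an epithelial surfactant gene in the lung, which rose by 3.19 on the log2 scale (SE 0.265). A loss of only some kinds of epithelial cell stays open for the falls, beside the hypothesis that Sin3a loss may change expression within epithelial cells, which RNA from sorted epithelial cells would test.

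DNA replication genes were lower by 20.7% at the median (log2 change -0.335, or -0.206 with globin and small RNA genes left out), with 5 of 35 that fell and an adjusted p of 0.058 with an estimated correlation. A GC or length trend as the whole cause of the lower median is argued against by the median after correction, -0.317 (bootstrap SD over the list's genes 0.033). With an estimated correlation, however, the camera adjusted p rose from 0.058 to 0.33 after that correction (unadjusted p = 0.0018 and 0.053). A lower share of epithelial cells, if these divide more than other lung cells, could give part of the fall and cannot be told apart here. The lung epithelium list fell by more, 43.8% in FPKM + 1, which understates falls of genes with low FPKM. With a pseudocount of 0.01 the median log2 changes were -1.09 for lung epithelium and -0.338 for DNA replication. The share of epithelial cells is not known. The rise of Cdkn1a is a biological alternative that may belong to the same change, and no test here separates the cell types in which either occurred.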
